A study of Homo sapiens with 4 samples.

How the data were processed

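ATAC-seq libraries were made from 75000 harvested cells per sample by Tn5 tagging, PCR and Illumina sequencing, per the labels' protocols. The labels give 2 knock-down and 2 control samples, numbered 1 and 2 in each group, and do not say whether the numbers stand for separate cultures. Reads were aligned with Bowtie 1.1.2 to hg19 and peaks were called with MACS2, per the submitters' processing notes. The MACS2 version and options, the treatment of duplicate reads and the pooling of replicates are not given in the sources used here. The 1 deposited list is in narrowPeak format, with a track line that names 225sh and RDsh. That 225sh stands for the multiH1 knock-down, and that the control was the reference, is an assumption from these names, since the labels do not use 225sh.

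The deposited fold enrichment is the ratio of signal to background at the summit. The p-value and q-value columns deposited by the authors hold −log10 values for the same summit. The deposited score equals 10 times −log10 p without its decimals in all 371521 lines, within 1 unit. The list repeats a region's start and end on a line for each of its summits. A line is called a summit here and a distinct start and end a region. Positions are hg19 and are counted from 1.

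The background was recovered as follows. Taking the fold as (pileup + 1) / (background + 1) and the p-value as the upper tail of a Poisson distribution above the pileup, the whole-number pileup under 400 reads that matched the listed p was found for each distinct pair of fold and p, with no assumption that pairs share a background. Pairs whose p is too small for ordinary floating point were solved in the same way, for pileups under 300000 reads and backgrounds under 50, from the logarithm of the tail. In 663 of these 691 pairs the pileup was the same as that from the fold and the common background, and in the others it differed by at most 23 reads. The pileups from the fold are used. The solver for ordinary p-values was tested on simulated data of 500 lines with 1 background and 500 lines with differing backgrounds, and recovered pileup and background in 100% of each. The clustering measure was tested on 20000 simulated uniform summits and gave a variance to mean ratio of 1.00.

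Densities of chromosomes are summits over the span from the first to the last listed region, with the centromere gap included. Densities of arms, and of the rest of a chromosome beside its ends, are over lengths without the centromere gap, as is the share of length in ends. The centromere gap is the stretch without listed regions around the known centromere position, taken to the nearest Mb. Windows lying wholly in it were left out of the counts of windows, but not of the clustering measure. Adjoining windows of the densest 10% form a block. Random placements put as many summits at uniform positions on each chromosome 100 times. Shares carry 95% Wilson intervals, which cover counting error only, since summits are not independent and PCR reads without molecular identifiers are not independent molecules. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

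Fixed before the data were examined were the counts, the densities by chromosome, the clustering measure and the rule for named items, which takes the 10 windows of 100 kb with the most summits, the 10 summits with the highest −log10 q, and genes by their promoter or body. Arms, blocks, ends, centromere flanks, wide regions and pileup classes were chosen after the data were seen. The remark on the mitochondrial copy on chromosome 1 is background knowledge of its location, chosen after the values were seen. The gene table used here is of GRCh38, another build than the list, and no genome or repeat annotation of the list's build was used. Therefore the planned shares of summits in promoters, intergenic sequence and repeats, and the GC content, were not analysed here. The same holds for the gene lists (interferon-stimulated, histone, luminal breast, housekeeping and others). No differential test was run, because the list has no value per sample.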

Results

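ATAC-seq, in which the Tn5 transposase cuts and tags open chromatin, was carried out on T47D-MTVL cells, a derivative of the T47D breast cancer line that carries a luciferase reporter under the MMTV promoter. The cells expressed either an shRNA against several linker histone H1 variants (the multiH1 knock-down, 2 samples) or a random shRNA (the control, 2 samples). Linker histone H1 binds the nucleosome and the DNA entering and leaving it, and the comparison addressed whether its loss changed DNA accessibility. For the 4 samples 1 list of peaks was available, whose track line names 225sh and a random shRNA (RDsh). The labels call the knock-down multiH1sh and do not use the name 225sh, so that both names mean the same cells, with the random shRNA as the reference, is an assumption made from the name of the list. The list gives no value per sample and does not say which of the samples went into it, so no spread between replicates can be set beside any value below, and no value below is a test of knock-down against control. The fold enrichments, p-values and q-values of single peaks are the authors'.

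The list held 371521 summits in 197823 regions, which covered 73.2 Mb of the hg19 genome. A summit is the point of highest signal in a peak, and 71.8% of regions had 1 summit, whereas the region with the most had 260. Regions were short, with a median of 208 bp, and ranged from 96 to 65337 bp. The median fold enrichment at the summit was 5.32, the 25th percentile 4.65, the 75th percentile 6.98 and the 99th percentile 21.6. The lowest fold was 3.66, and the lowest −log10 q was 3.29, so neither a fold minimum of 2 nor a q-value of 0.01 removed any summit.

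The fold and the p-value of a summit together gave its pileup, the number of reads over it, and the background it was scored against. In 370182 summits (99.6%) both could be solved, and each gave a whole number of reads over a background of 2.01 reads, with a range of 5.03e-06 between the lowest and the highest solved background. The other 1339 summits had p-values below the range of ordinary floating point. Solved from the logarithm of the Poisson tail, they gave backgrounds from 2.00701 to 2.00784 reads, matching the listed −log10 p within 1.97 at values up to 1141325. With the common background the folds of all summits gave whole pileups (tolerance 0.02 reads), which are used below. Pileups ran from 10 to 245280 reads with a median of 15, and 26.5% of summits had 20 reads or more. A summit of 9 reads would have had a −log10 p of 4.32, below the lowest listed value of 5.07. Because all solved summits shared 1 background, the fold of a region was a multiple of a genome-wide read level and not of the level of the control cells at that region. The list therefore ranked regions by their own read pileup, and the size of a difference from the control at any region was not measurable from it. The total reads per sample were not given in the sources used here, and the background of 2.01 reads is the only measure of depth behind these values.

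The first question was where in the genome the listed regions lay. Chromosome 17 was the most densely covered, with 40035 summits or 493 per Mb, against 124 per Mb over all chromosomes. It held 10.8% of all summits (95% Wilson interval 10.7 to 10.9%, counting error only). Chromosome 16 followed with 310 summits per Mb, chromosome 19 with 229, chromosome 22 with 215 and chromosome 20 with 200 (199.7). Chromosomes 17, 19 and 22 are known as gene-rich, but gene density was not measured here for any chromosome. At the other end, chromosome Y had 13.8 summits per Mb and chromosome X had 14.2. Next came chromosome 18 with 21.5, chromosome 13 with 33.9, chromosome 2 with 34.9, chromosome 4 with 45.7 and chromosome 6 with 48.5. The summits on chromosome Y lay in only 154 regions and had a median fold of 26.6, against 5.32 over all summits. Among chromosomes 1 to 22 and X the density thus varied 34.7-fold, from X to 17, or 21.7-fold with each region counted once. Of the 5 densest of these chromosomes 4 were still among the 5 densest when each region was counted once, and all 5 of the least dense were. Among the 50% of summits with the highest fold, 3 of the 5 densest and 4 of the 5 least dense were kept.

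The long arm of chromosome 17 had 621 summits per Mb, the short arm of chromosome 16 had 364, the long arm of chromosome 9 had 355, the long arm of chromosome 16 had 346 and the long arm of chromosome 20 had 339. The 2 arms of chromosome 9 stood far apart, at 355 summits per Mb on the long arm and 16.4 on the short arm. Chromosome 4 showed the opposite order, with 153 summits per Mb on the short arm and 8.31 on the long arm, the lowest of 43 arms of at least 2 Mb. Not ranked with these is the listed part of the short arm of chromosome 21, which had 771 summits in 1.76 Mb, or 439 per Mb. Chromosome 6 had 116 summits per Mb on its short arm, with dense windows from 31 to 32, 33 to 35, 41 to 42 and 43 to 44 Mb, and 13.4 on its long arm. The long arm of chromosome X had 12.1 and the short arm of X 18.4.

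Within chromosomes the summits were concentrated in few windows. Of 2944 windows of 1 Mb, the densest 10% (294 windows, each with at least 332 summits) held 65.9% of all summits (95% Wilson interval 65.8 to 66.1%). The median window had 21 summits and the mean window 126, and 206 windows had none. Adjoining dense windows formed 124 blocks with a median length of 1.5 Mb, of which 62 were single windows and 14 were 5 Mb or longer. The largest block lay on the long arm of chromosome 9 from 126 to 141 Mb, with 22336 summits or 80.9% of that chromosome's total. The 1 Mb window before it had 118 summits, against a mean of 1489 per Mb inside. Only the last window of the chromosome, which is cut short, followed the block, and it had 98 summits. The distal part of the long arm of chromosome 17, from 71 Mb to the last listed region at 81195060, held 15900 summits. A second block on the same arm, from 34 to 49 Mb, held 11476. The end of the long arm of chromosome 8 from 140 to 146 Mb held 11169, and chromosome 16 held 10430 from 84 to 90 Mb and 7744 in its first 5 Mb. Other large blocks covered chromosome 14 from 100 to 107 Mb (6940 summits), chromosome 11 from 63 to 71 Mb (6756) and chromosome 21 from 43 to 48 Mb (4476, or 70.7% of that chromosome). Chromosome 18 was the only chromosome with no window in the densest 10%.

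**Figure D1:**
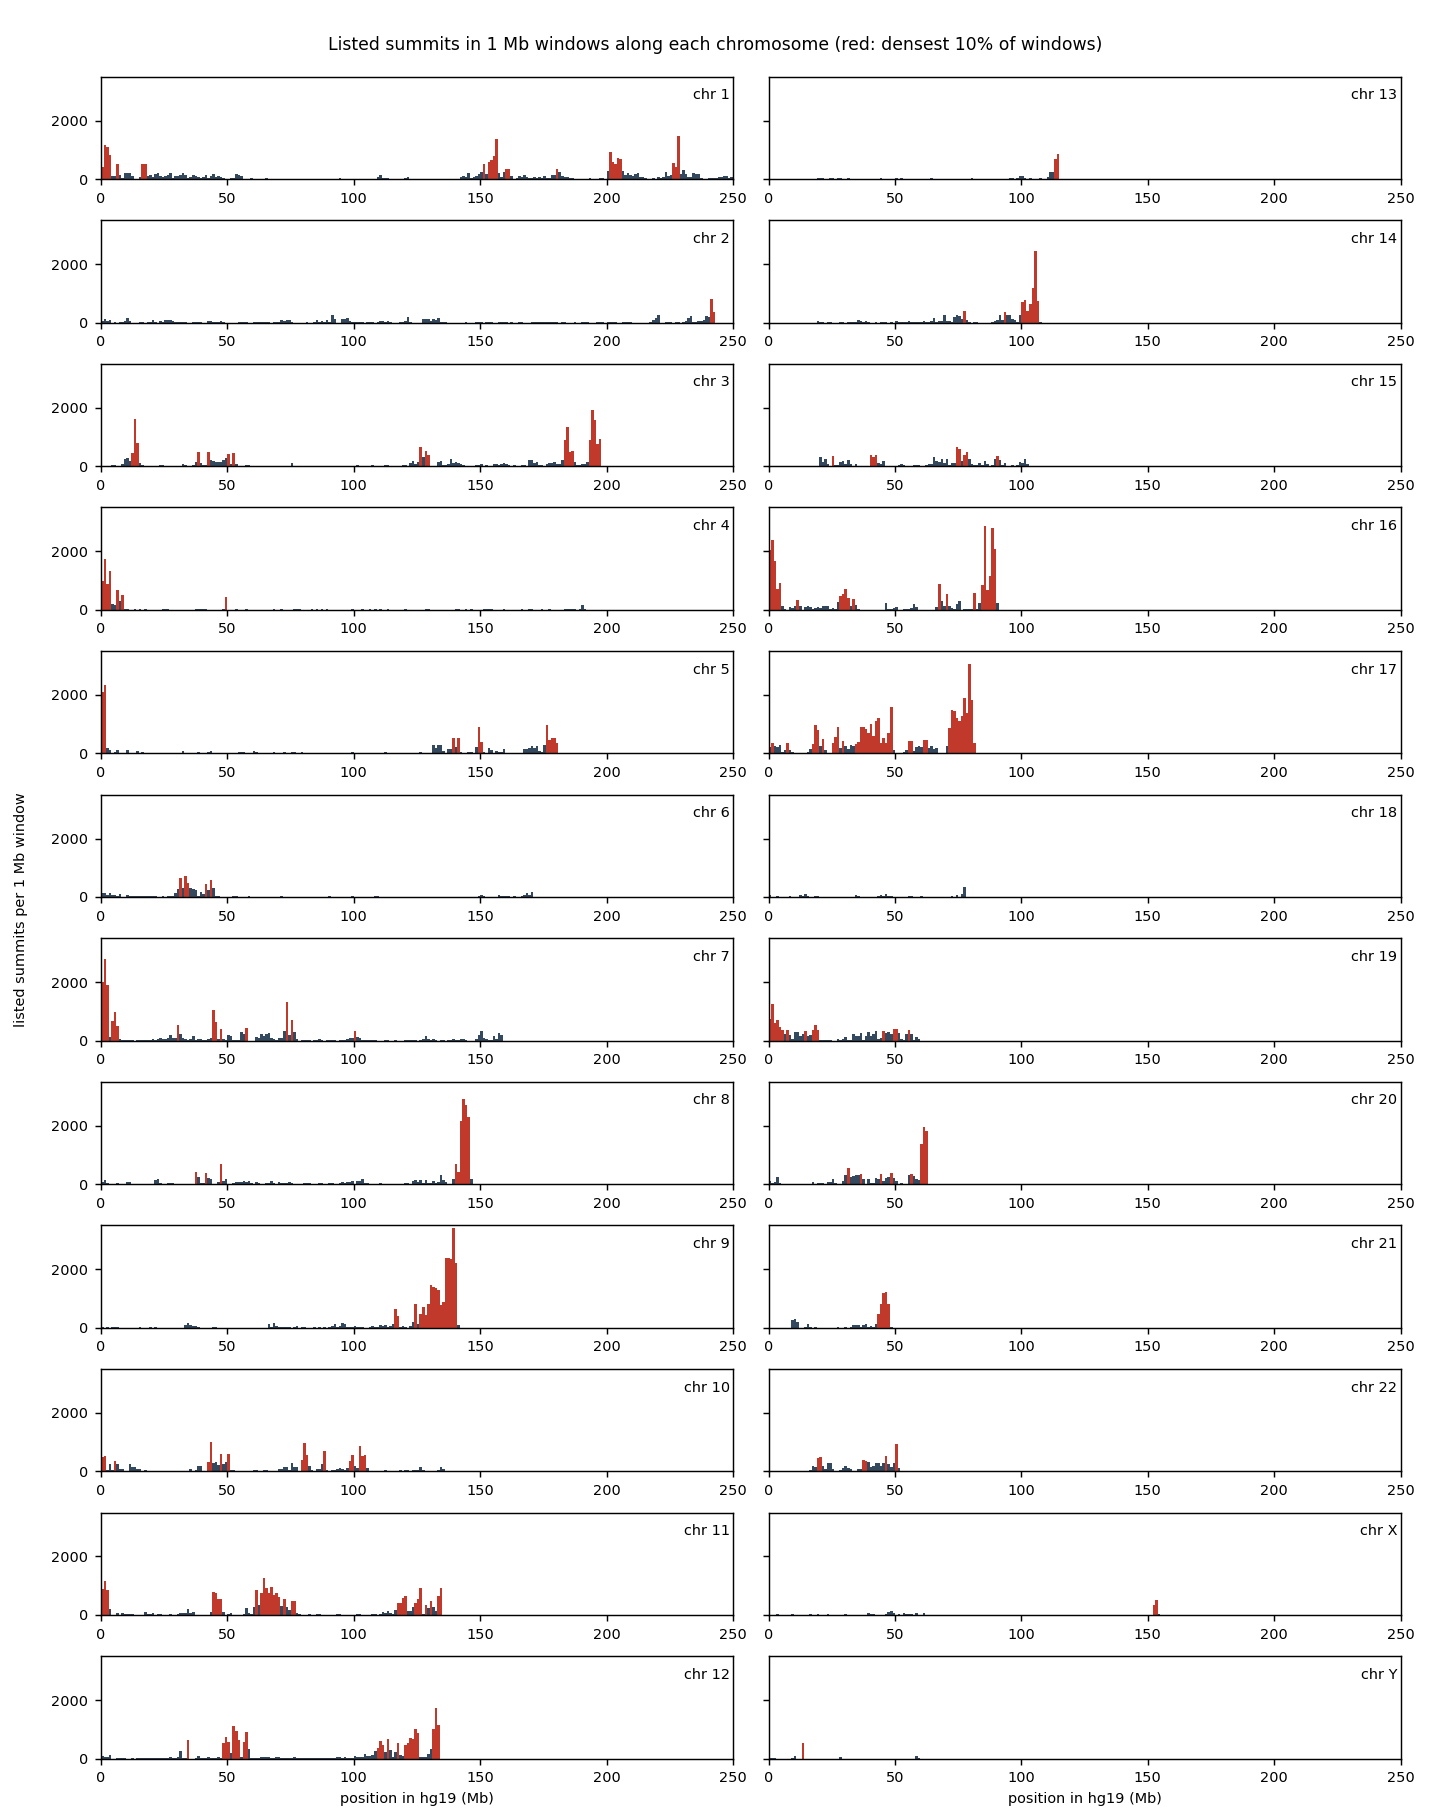
Number of listed summits (vertical axis) in each 1 Mb window along the hg19 chromosomes (horizontal axis, Mb), one panel per chromosome, with the densest 10% of windows in red. The red windows hold 65.9% of summits and gather in blocks, such as 126 to 141 Mb on chromosome 9, while most windows of chromosomes 18, X and 4 stay low, apart from blocks such as 152 to 154 Mb on X and the first 4 Mb of chromosome 4.

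The 10 windows of 100 kb with the most summits lay in these blocks, 5 of them on chromosome 16 and 3 on chromosome 9. The window from 85600001 to 85700000 on chromosome 16 had 531 summits with a median fold of 9.64, and its neighbours from 85400001 to 85500000 and from 85500001 to 85600000 had 496 and 478. The window from 88500001 to 88600000 on the same chromosome had 509, and that from 137200001 to 137300000 on chromosome 9 had 473. The variance of the number of summits per 100 kb window was 110 (109.7) times its mean. In 100 random placements of as many summits within each chromosome this ratio was 7.95 ± 0.0103 (SD over placements), with a highest value of 7.98. With placements kept outside the centromere gap the ratio was 9.03, with a highest value of 9.05. Neighbouring summits lay a median of 337 bp apart, against 4116 bp (SD 7.003) in the first placements and 3915 bp in those outside the gap. Part of this closeness comes from several summits within 1 region. With each region counted once the ratio was 32.3 against 4.01 in placements of as many regions. Uniform placement ignores where reads can be placed, so these values show only that the summits were spread unevenly.

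Chromosome ends were a main site of the listed summits. The terminal 5 Mb of 41 chromosome ends (all arms with a listed end except the short arms of the acrocentric chromosomes and chromosome Y) had 611 summits per Mb, against 92.9 in the rest of these chromosomes, a ratio of 6.58. Single ends differed widely, with a median ratio of 3.57 to the rest of their own chromosome and 21 ends at over 3 times it. These ends made up 7.20% of the length and held 33.8% of the summits. The ends were denser than the rest of their own chromosome in 32 of 41 cases, in 21 of 23 long arms and in 11 of 18 short arms. The densest were the ends of the long arms of chromosome 9 (2531 summits per Mb), chromosome 8 (2116), chromosome 16 (1901) and chromosome 17 (1899), and the short-arm ends of chromosome 16 (1561) and chromosome 7 (1497). The short-arm end of chromosome 4 had 1029 summits per Mb, 54.4 times the rest of that chromosome. In contrast, the short-arm end of chromosome 9 had 11.8 summits per Mb, that of chromosome 3 had 115 summits in its 5 Mb and the long-arm end of chromosome 10 had 56.6 per Mb, each below the rest of its chromosome. With each region counted once the ratio of ends to the rest was 4.43.

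**Figure D2:**
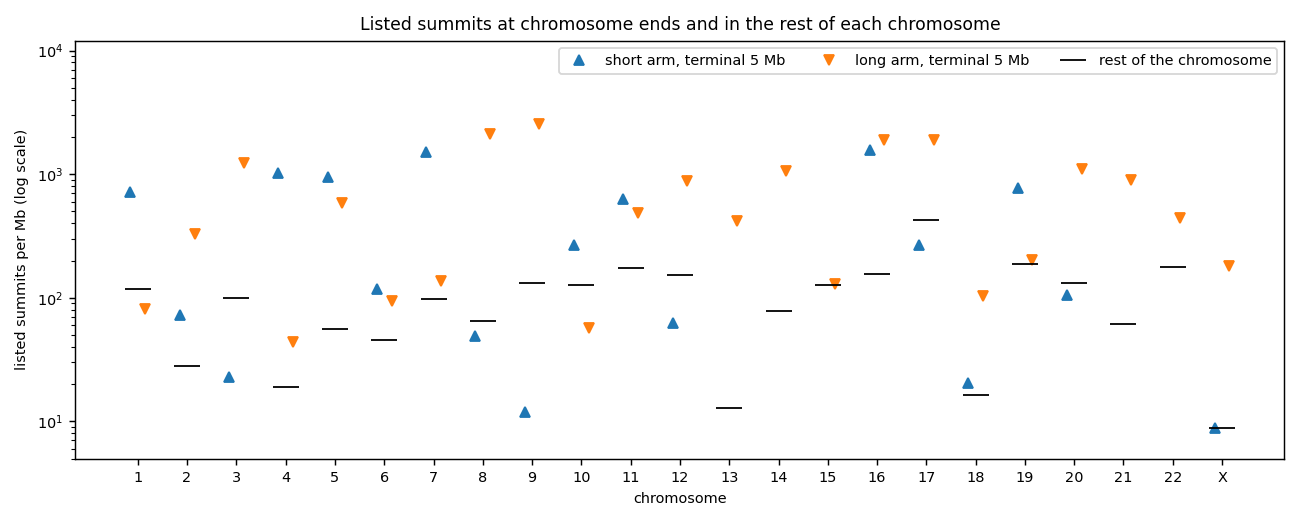
Listed summits per Mb (vertical log axis) in the terminal 5 Mb of the short arm (upward triangles) and long arm (downward triangles) and in the rest of each chromosome (bars), for chromosomes 1 to 22 and X (horizontal axis). The triangles lie above the bar of their chromosome at 32 of 41 ends, with the long-arm end of chromosome 9 the highest at 2531 summits per Mb.

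Strong summits were placed differently from the bulk. Within 2 Mb of the stretch without listed regions that spans each centromere (the centromere gap) lay 43.1% of the 5358 summits of 50 reads or more (95% Wilson interval 41.8 to 44.5%), but 2.79% of the 273088 summits under 20 reads (2.73 to 2.85%). These flanks made up 3.02% of the spanned length. Of the summits of 100 to under 1000 reads, 64.5% lay there, but of the 244 summits of 1000 reads or more 33.2% did (27.6 to 39.3%). Of the strong summits beside gaps, chromosome 10 contributed 448, chromosome Y contributed 365, chromosome 4 contributed 334, chromosome 21 contributed 201 and chromosome 16 contributed 187. Few regions held many of them: with each region counted once by its highest summit, 12.6% of 1542 regions of 50 reads or more lay beside a gap (11.02 to 14.3%), against 2.77% of regions under 20 reads. In the dense windows of 1 Mb the median fold was 5.65, against 4.99 in the other windows, and the 90th percentile was 8.98 against 8.31. Summits of 20 reads or more made up 29.86% of those inside the dense windows and 19.995% of those outside, whereas summits of 50 reads or more made up 1.07% inside and 2.16% outside. Among summits over 2 Mb from a centromere gap these shares were 29.5% and 18.6% at 20 reads or more, and 0.643% and 1.27% at 50 reads or more.

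**Figure D3:**
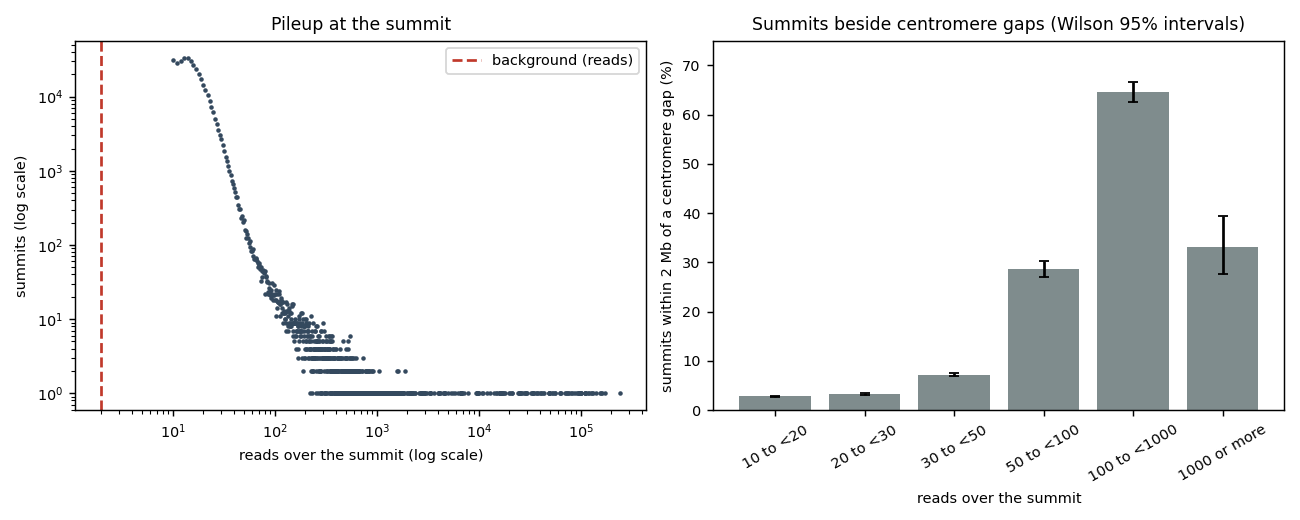
Left, number of summits (vertical log axis) at each pileup in reads (horizontal log axis), with the background of 2.01 reads as a dashed line. Right, percentage of summits within 2 Mb of a centromere gap (bars, with 95% Wilson intervals) by pileup class, which is 2.79% at 10 to under 20 reads, 64.5% at 100 to under 1000 reads and 33.2% at 1000 reads or more.

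Of the 20 widest regions 16 lay within 2 Mb of a centromere gap, but of all 86 regions of 10 kb or more 32 did (37.2%, 95% Wilson interval 27.7 to 47.8%), and of the 2909 regions of 2 to under 10 kb 7.18%. The widest was on chromosome 4 from 49093292 to 49158628 (65337 bp, 211 summits), followed by chromosome 12 from 34481902 to 34536978 (55077 bp, 260 summits), chromosome 10 from 38772917 to 38818805 (45889 bp) and chromosome 21 from 10773867 to 10817547 (43681 bp). Such flanks are known to carry satellite repeats, but no repeat annotation was used here. The widest regions away from the gaps lay in the dense blocks of chromosome 16 (85656885 to 85686796, 29912 bp) and chromosome 8 (144449465 to 144477084, 27620 bp).

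The 10 summits with the highest −log10 q all lay in 1 region of chromosome 1 from 564460 to 570307, known as a nuclear copy of mitochondrial DNA. Their folds ran from 39621 to 81555 and their pileups from 119162 to 245280 reads. The next regions by fold were chromosome 5 from 134258619 to 134264215 (highest fold 37397), chromosome 5 from 79945840 to 79948188 (36838) and chromosome 11 from 10529433 to 10531882 (25204). In all, 244 summits in 59 regions had 1000 reads or more. Some of these were single narrow summits, such as chromosome 18 from 45379617 to 45379810 (194 bp, fold 12499.5) and chromosome 2 from 49456766 to 49457038 (273 bp, fold 11303).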

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

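All alternatives for the densest 10% of windows, chromosome ends and centromere flanks, those at 20 reads or more, without summits above 192 reads, with each region counted once other than for the number of peaks, and outside the centromere gap were chosen after the data were seen. The number of peaks was 371521, and became 197823 with lines of the same start and end counted once, 185760 in the 50% with the highest fold and 98433 at 20 reads or more, each by construction. It stayed within 1.5 times under 4 other alternatives, of which the q-value of 0.01 and the fold of 2 removed no summit and so test nothing. The ratio of the densest to the least dense chromosome was 35.7 and ran from 21.7 to 85.1, with 21.7 with each region counted once on chromosomes 1 to 22 and X only, 48.4 in the 50% with the highest fold, 84.9 with regions within 100 bp merged and 85.1 with each region counted once. Chromosome 17 was densest under all of these. The least dense was chromosome Y or X. The values near 85 rest on chromosome Y, whose 154 regions are few and whose summits had a median fold of 26.6. The variance to mean ratio of 109.7 became 90.7 in the 50% with the highest fold, 31.6 with regions merged, 32.3 with each region counted once, 739 in windows of 1 Mb and 16.7 in windows of 10 kb, and lay above its random placements in each (at most 5.19, 3.99, 4.04, 70.9 and 1.71). The share in the densest 10% of windows (65.9%) was 75.8% in windows of 100 kb, 55.8% with each region counted once, 76.3% at 20 reads or more and 66.4% without chromosome 17. The ratio of chromosome ends to the rest (6.58) was 4.61 for the terminal 10 Mb, 7.51 for the terminal 2 Mb, 4.43 with each region counted once and 10.04 at 20 reads or more. The share of strong summits beside centromere gaps (43.1%) was 39.2% within 1 Mb, 61.3% at 100 reads or more, 40.04% on chromosomes 1 to 22 and X only and 12.6% with each region counted once. Apart from those that follow from the construction, the causes of these shifts were not tested. Chromosome ends stayed denser than the rest in each alternative. The share of strong summits beside gaps stayed above the 3.02% of the spanned length that lies within 2 Mb of a gap. The number of peaks, the ratio between chromosomes and the share in the densest 10% of windows have no direction that could change. No paired analysis was possible because the list has no value per sample, and replicates could not be left out for the same reason. The promoter, intergenic, repeat, GC and gene list alternatives, and densities over a genome's length without N, were not run. The gene table used here is of another build, and no genome or repeat annotation of this build was used. The cut-off at 10 reads over a background of 2.01 reads limits the list: regions with fewer reads are not listed, so a low count in a window does not show closed chromatin.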

Other observations

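All tests in this part were chosen after the result was seen. The longest stretch without any listed region, outside the centromere gaps on chromosomes 1 to 22 and X, was on chromosome X from 84258887 to 93959492 (9.70 Mb), followed by chromosome 4 from 30724577 to 35910323 (5.19 Mb) and chromosome X from 95939795 to 100353002 (4.41 Mb). Of 235 such stretches of over 1 Mb, chromosome 2 held 36, chromosome 4 held 33 and chromosome X held 31. Chromosome 22 and chromosome 21 held 1 each, and chromosomes 15, 17 and 19 held none. These counts are not adjusted for the length of the chromosome. Nor do they allow for unknown sequence outside the centromere gaps or for sequence where reads cannot be placed. The stretches on chromosome X added up to 71.5 Mb.

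On chromosome X, 859 of the 2200 summits (39.0%) lay from 152 to 154 Mb, after a window of 11 summits. On chromosome 13, 1517 summits (46.7%) lay from 113 to 115 Mb. Of the 20 largest blocks, 15 reached the terminal 5 Mb of a chromosome.

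The first pattern weighed is the megabase blocks. A pair of technical accounts was set against bounds, each only as the whole cause. Arms held 34.4% of the variance of log2(summits + 1) over 1 Mb windows. This was less than the 50% set for copy number of whole arms as the whole cause. Differences between windows of the same arm lower this share whatever the copy number, so falling below the bound also decides little. With each region counted once, 55.8% of regions lay in the densest 10% of windows, above the 20% bound set for repeated summits of wide regions. That bound does not allow for differences in density between chromosomes, so passing it decides little. The share was 65.9% for summits, so much of the concentration remained without repeated summits. A single background for the whole genome, with no local or control term, may let any regional rise in read density reach the list, and the backgrounds solved by ordinary arithmetic, in 99.6% of summits, differed by only 5.03e-06. Because no genome of this build and no input were used here, other accounts stay open and were not tested. They are whole-arm copy number as part of the cause, copy number of shorter segments, and read density that follows GC content or gene density. A local gain of accessibility on H1 knock-down cannot be told apart from these, because the list carries 1 background value and no control level.

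The second pattern is the summits with very high pileup. If reads had been kept once per start and strand, a pileup over fragments as long as the shortest region (96 bp) could not exceed 192 reads in 1 library, and 1365 summits in 201 regions did, of which 520 summits in 129 regions lay over 2 Mb from a centromere gap and so outside the third pattern. Pooling of replicates is not given in the sources used here. With 2 libraries pooled the limit is 384 reads, which 656 summits in 110 regions exceeded, and with all 4 it is 768, which 306 summits in 70 regions exceeded (311 and 180 summits over 2 Mb from a gap). This is consistent with reads of the same start being kept. Fragments longer than 96 bp would raise these limits, but not to the 245280 reads seen. Reads of the mitochondrial genome placed on nuclear copies are a candidate source, with 0 listed lines on the mitochondrial genome itself, but no sequence was used here to match the regions, so this stays open.

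The third pattern is the strong summits beside the centromere gaps. The share beside a gap was 15.5 times higher at 50 or more reads than under 20 reads, or 4.55 times with each region counted once. No value at hand decides between accounts of it. Repeat copies that the assembly holds in too few places stay open, because the list has 0 columns that give a repeat class and no repeat annotation was used here. More accessible satellite repeats on H1 knock-down also stay open, since the list has 1 background value and no control level there.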
